A study of Mus musculus with 15 samples.

How the data were processed

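The series holds 15 bulk RNA libraries from sorted STR-KI mouse cells in 8 groups, with 3 libraries in 2 groups, 2 libraries in 3 groups and 1 library in 3 groups. Per the labels, total RNA was extracted on beads, and libraries were made with oligo-dT priming, unique molecular identifiers and tagmentation. The authors aligned reads with STAR 2.7 to GRCm39 and used SAMtools 1.21; the gene annotation, the counting step and the handling of reads with several locations are not given in the sources used here. The deposited table holds CPM values for 78409 rows, and every library sums to 1000000 over all rows.

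Of these rows, 21909 have no gene name and 92 are ERCC spike-in rows, and both were left out. The 627 rows that share 311 symbols were summed by symbol, which left 56092 named genes. Genes carry the symbols of the table, which gives no positions. The most common nonzero value of a library, refined on its larger values, was taken as the step of 1 read. This step gave the depth of each library, and the floor was set at 3 reads. Of the nonzero values, 71.1 to 78.7% per library were whole multiples of that step within 0.01 reads, and 97.8 to 98.8% were multiples of a 12th of it. Whole reads were not recovered, and the edgeR test, planned for whole reads, was not run.

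The tests used limma 3.58.1 in R 4.3.3 (limma-trend with robust moderation, two-sided) on log2(CPM + 1). One fit held all 15 libraries in 8 groups with 7 residual degrees of freedom, so groups with 1 library took the spread of the replicated groups. Genes with at least 5 CPM in at least 2 libraries were tested, 12943 in all, with Benjamini-Hochberg adjustment per comparison and a threshold of 0.05. Of the 10 comparisons, 2 averaged over a further factor and 1 was a difference of differences. Because the labels do not state what a library number stands for, no replicate block entered the main model.

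Before the data were examined, 33 gene lists with 386 members were fixed, of which 292 members passed the filter. The 31 lists with at least 4 tested genes were tested with camera at its preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. A companion test, fry, was run on the same lists. The preset correlation gave 134 calls in 310 tests and the estimated correlation 16, and each list result is printed with both. Sox2 and Tbxt, the sorted reporters, are in no list.

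Genes were named by a rule fixed beforehand. It takes Sox2 and Tbxt first. It then takes, in each direction, the 8 largest changes past the threshold with libraries that do not overlap and a mean of at least 20 CPM in the higher group. Up to 4 passing members per list with the largest changes complete it. The text leaves out part of these genes for length, some withheld genes are not reported here, and those that changed sides under an alternative were left out except for the reporters.

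Simulated libraries with the depths and groups of the series, 200 changed genes and a dispersion of 0.01 were put through the same fit. By comparison, 56 to 91% of 2-fold and 91 to 100% of 4-fold changes were recovered, with 0 to 13 false calls in 8 comparisons. FGF Sox2+ against Sox2 48 h cells gave 60, and Tbxt 7 d against FGF Sox2+ cells gave 70. The data may vary more, so recovery may be overstated and false calls understated.

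Alternatives fixed beforehand were other pseudocounts, no filter or a stricter one, median-of-ratios scaling, quantile normalization, array weights, a fit of the compared groups alone, a 2-fold minimum, a block on the library number and leaving out each replicate. A voom fit on reads inferred from the step and list tests without either of 2 libraries were added after the data were seen. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and R used statmod 1.5.0 and data.table (version 1.17.8).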

Results

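RNA was sequenced from sorted populations of STR-KI, a mouse embryonic stem cell line in which an allele of Sox2 carries mCherry and an allele of Tbxt, the gene of Brachyury, carries GFP. The cells were brought to a neuromesodermal progenitor (NMP) state by 48 h in 10 ng/mL FGF2 and a further 24 h in FGF2 with 5 µM CHIR, an activator of WNT signalling. NMPs are progenitors of the caudal embryo that can form spinal cord or paraxial mesoderm. Cells positive for both reporters formed the NMP group (3 libraries). After 48 h of further culture in FGF/CHIR, cells positive for mCherry (Sox2 48 h cells, 2 libraries) or for GFP (Tbxt 48 h cells, 2 libraries) were sorted. Sox2-derived cells were then cultured for 7 d in FGF/CHIR or in FGF alone and sorted as mCherry-positive (Sox2+) or double negative (DN). These groups held 2 libraries for FGF Sox2+ and 1 library each for FGF/CHIR Sox2+, FGF/CHIR DN and FGF DN. Tbxt-derived cells were cultured for 7 d in FGF/CHIR and sorted as DN (Tbxt 7 d cells, 3 libraries). The labels do not state whether libraries of a group or medium came from separate cultures. Groups with 1 library have no replicate check. A p from a comparison with such a group rests on the spread of other groups and cannot separate the group from its library.

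The values were counts per 1000000 (CPM) for 56092 named genes. The most common nonzero value of a library, taken as 1 read, gave 3.43 to 9.88 M reads (M, 1000000) in 14 libraries, with 3 reads at 0.304 to 0.874 CPM. FGF Sox2+ replicate 2 held 0.8 M reads, with 3 reads at 3.76 CPM. These floors cover counting error only. A level in CPM is the mean ± SD over the libraries of a group, or the value of the single library. A value with ± after a gene is its log2 fold change ± SE, first group over second, in a limma fit of all 15 libraries, and genes with at most 3 reads on one side are given as levels. "Rose", "fell", "higher" and "lower" refer to genes with an adjusted p under 0.05. Sox2 stood at 209.7 ± 40.5 CPM in NMPs, 219 ± 2.62 CPM in Sox2 48 h cells and 36.4 ± 3.01 CPM in Tbxt 48 h cells, and Tbxt at 387 ± 89.3, 30.7 ± 1.98 and 219 ± 4.64 CPM. At 7 d, Sox2 was 389 ± 1.49 CPM in FGF Sox2+ cells and 199 CPM in FGF/CHIR Sox2+ cells, against 29.1 and 5.03 CPM in FGF and FGF/CHIR DN cells and 0.57 ± 0.78 CPM in Tbxt 7 d cells.

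**Figure D1:**
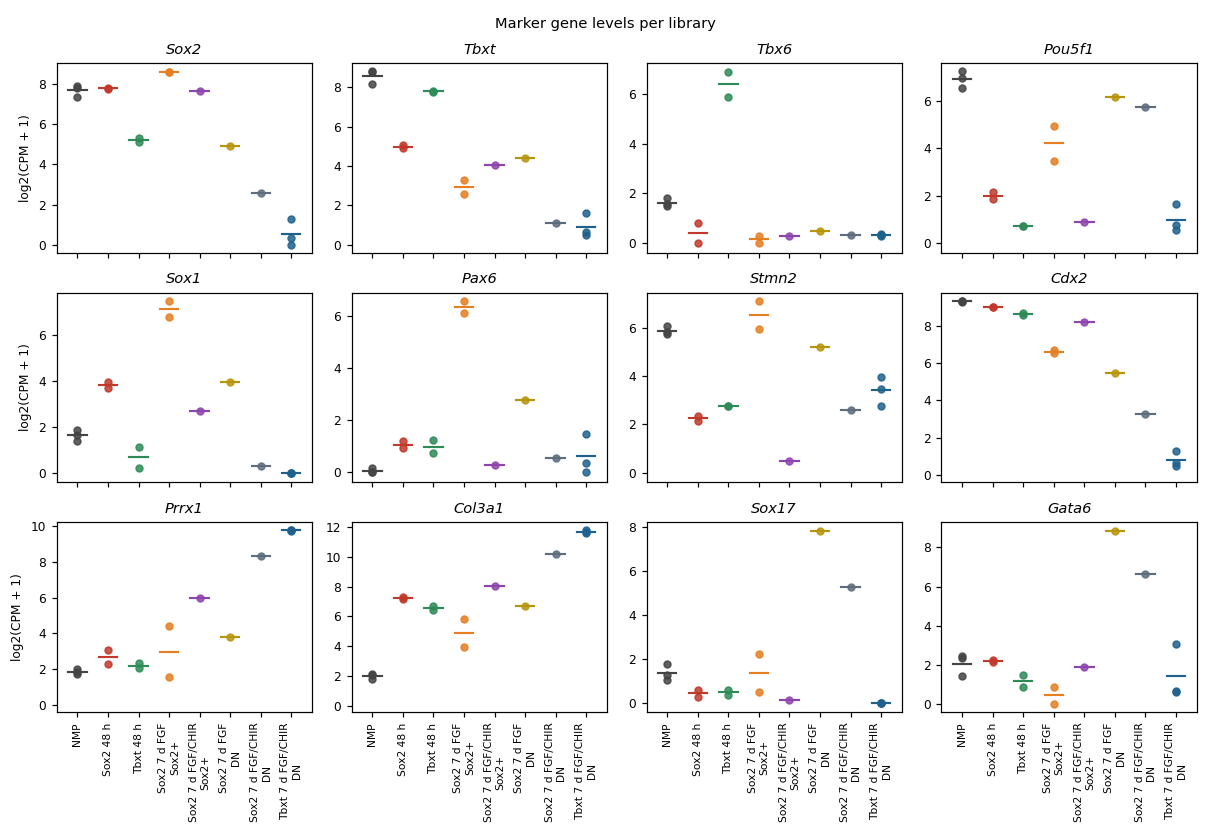
Levels of 12 marker genes as log2(CPM + 1), with a point per library and a line at the group mean. Tbx6 was highest in Tbxt 48 h cells, Sox1 and Pax6 in FGF Sox2+ cells at 7 d, Sox17 and Gata6 in the DN cells of Sox2-derived cultures, and Prrx1 and Col3a1 in Tbxt 7 d cells.

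The first comparison asked what changed in cells that kept the Sox2 reporter for 48 h. Sox2 differed by 0.08 ± 0.30 from NMPs (adjusted p = 0.921), while Tbxt (−3.59 ± 0.33) fell. Caudal epiblast genes fell with it: Wnt3a (0 against 69.2 ± 4.93 CPM), a WNT ligand of the caudal epiblast, was listed at 0 in Sox2 48 h cells, and Wnt8a (−3.22 ± 0.31), Fgf8 (−3.51 ± 0.39), Cdx1 (−2.99 ± 0.35) and the retinoic acid-degrading enzyme gene Cyp26a1 (−3.51 ± 0.22) were lower. The NMP and caudal epiblast list fell in 7 of 15 measured genes, with 1 higher (camera adjusted p = 1.8e-06, adjusted p = 0.044 with an estimated correlation). Without FGF Sox2+ replicate 2, that adjusted p with an estimated correlation was 0.077. The pluripotency factor gene Pou5f1 (−4.92 ± 0.41), the cadherin gene Cdh1 (−3.84 ± 0.34), Utf1 (−2.90 ± 0.41) and the epithelial gene Epcam (−2.93 ± 0.30) were lower. The epiblast list fell in 6 of 10 measured genes (camera adjusted p = 1.7e-06, adjusted p = 0.31 with an estimated correlation). Naive pluripotency genes fell in 4 of 10 measured genes (camera adjusted p = 0.00089, adjusted p = 0.31 with an estimated correlation).

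Neural progenitor genes rose in the same cells: Pou3f2 (3.30 ± 0.30), Zic1 (2.76 ± 0.36) and Sox1 (2.19 ± 0.33), transcription factor genes of neural progenitors, were higher. The neural progenitor list rose in 3 of 12 measured genes (camera adjusted p = 1.7e-06, adjusted p = 0.042 with an estimated correlation). Without Tbxt 7 d replicate 1, that adjusted p with an estimated correlation was 0.057. Neuronal genes, with Stmn2 (−3.64 ± 0.35) among them, were lower in 3 of 11 measured genes, with 1 higher (camera adjusted p = 0.011, adjusted p = 0.53 with an estimated correlation). More 5′ Hox genes, which mark more posterior axial levels, were higher, among them Hoxc10 (6.13 ± 0.38), Hoxa10 (3.43 ± 0.25), Hoxc9 (2.41 ± 0.20), Hoxc6 (2.15 ± 0.22) and Hoxa9 (2.15 ± 0.20). Hoxb1 (−3.72 ± 0.38) fell. Paralogs 5 to 9 rose in 6 of 14 measured genes (camera adjusted p = 1.7e-06, adjusted p = 0.052 with an estimated correlation). Hox paralogs 10 to 13 rose in 4 of 11 measured genes (camera adjusted p = 1.4e-05, adjusted p = 0.26 with an estimated correlation). The BMP-responsive genes Id2 (1.65 ± 0.17) and Id3 (1.55 ± 0.23), the collagen gene Col3a1 (5.21 ± 0.41), the guidance factor gene Sema3a (3.05 ± 0.23) and the imprinted genes Igf2 (3.25 ± 0.45) and Peg12 (2.95 ± 0.40) rose. The follistatin gene Fst (−5.42 ± 0.32), the retinoic acid-responsive gene Stra8 (−3.57 ± 0.35) and the cyclin gene Ccnb2 (−1.02 ± 0.15) fell. Proliferation genes were lower in 4 of 13 measured genes (camera adjusted p = 1.7e-05, adjusted p = 0.26 with an estimated correlation). The higher and lower counts adjusted over the list alone were 2 and 8 (NMP and caudal epiblast), 0 and 6 (epiblast) and 0 and 7 (naive pluripotency). For further lists they were 6 and 0 (neural progenitor), 1 and 3 (neuron) and 9 and 2 (Hox paralogs 5 to 9). Counts of further lists were 5 and 0 (Hox paralogs 10 to 13) and 0 and 8 (proliferation). Called higher by camera too: mesenchyme (2 higher and 1 lower of 11, 4 and 1 adjusted over the list alone, adjusted p = 0.039) and BMP and TGFb targets (2 higher and 0 lower of 11, 2 and 0 adjusted over the list alone, adjusted p = 0.0041). The camera calls of higher lists included immediate early and stress (1 higher and 0 lower of 9, 1 and 0 adjusted over the list alone, adjusted p = 0.025). Presomitic mesoderm (0 higher and 2 lower of 9, 1 and 5 adjusted over the list alone, adjusted p = 0.03) and retinoic acid (1 higher and 4 lower of 10, 1 and 4 adjusted over the list alone, adjusted p = 0.003) were lower by camera as well. Hypoxia and glycolysis (0 higher and 3 lower of 11, 1 and 4 adjusted over the list alone, adjusted p = 0.025) was also lower by camera. The lowest adjusted p of these lists with an estimated correlation was 0.31. Lists without a camera call held 3 higher and 2 lower of 12 (Hox paralogs 1 to 4, 3 and 3 adjusted over the list alone, adjusted p = 0.43) and 0 higher and 3 lower of 10 (epithelium, 2 and 3 adjusted over the list alone, adjusted p = 0.19).

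In all, 1025 of 12943 genes differed, 343 higher and 682 lower. The count was 622 without NMP replicate 2, 556 without NMP replicate 3, 516 without Sox2 48 h replicate 1 and 316 without Sox2 48 h replicate 2. The 29 named genes past the threshold had adjusted p of at most 0.00225.

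The next comparison asked the same of cells that kept the Tbxt reporter. Sox2 (−2.48 ± 0.30) was lower in Tbxt 48 h cells than in NMPs, and Tbxt differed by −0.79 ± 0.33 (adjusted p = 0.115), which passed at a pseudocount of 4 (adjusted p = 0.0312), with array weights (0.0143) and in the fit of these groups alone (0.0151). Over all alternatives its adjusted p ranged from 0.00705 to 0.403. Presomitic mesoderm genes rose: Tbx6 (4.78 ± 0.38), the transcription factor gene of presomitic mesoderm, Dll1 (4.08 ± 0.44), Lfng (3.63 ± 0.28) and Cited1 (3.25 ± 0.33) were higher. The list rose in 7 of 9 measured genes (camera adjusted p = 3.6e-08, adjusted p = 0.12 with an estimated correlation). Genes of the Notch pathway, which drives the segmentation clock, rose in 9 of 10 measured genes (camera adjusted p = 3.6e-08, adjusted p = 0.33 with an estimated correlation), with Nrarp (2.42 ± 0.34) and Hey2 (2.32 ± 0.40) among them. Snai1 (4.02 ± 0.25), a repressor gene of the epithelial state, and Cdh2 (1.07 ± 0.19) rose, and Cdh1 (−6.10 ± 0.34), Epcam (−5.14 ± 0.30), Cldn6 (−3.04 ± 0.29) and Esrp1 (0.05 ± 0.07 against 4.87 ± 0.76 CPM) fell. Epithelial genes were lower in 6 of 10 measured genes (camera adjusted p = 2.6e-05, adjusted p = 0.34 with an estimated correlation).

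Pluripotency genes were lower, with Pou5f1 (−6.19 ± 0.41), Utf1 (0.05 ± 0.07 against 30.0 ± 10.0 CPM), Pou3f1 (−3.35 ± 0.44), Klf5 (−3.17 ± 0.39) and Dppa5a (−6.39 ± 0.94) among them. The naive pluripotency list fell in 8 of 10 measured genes (camera adjusted p = 2.9e-05, adjusted p = 0.34 with an estimated correlation). The epiblast list fell in 5 of 10 measured genes (camera adjusted p = 2.6e-05, adjusted p = 0.43 with an estimated correlation). Caudal epiblast genes moved both ways: Wnt8a (0.10 ± 0.14 against 12.9 ± 1.41 CPM), Cdx1 (−2.71 ± 0.35) and Nkx1-2 (−2.46 ± 0.27) fell, while Gdf11 (2.07 ± 0.20) and Cyp26a1 (1.37 ± 0.22) rose. The list was higher in 3 and lower in 7 of 15 measured genes (camera adjusted p = 0.044, adjusted p = 0.35 with an estimated correlation). Among neural genes, Sox3 (−2.91 ± 0.28) and Stmn2 (−3.12 ± 0.35) fell and Fabp7 (2.48 ± 0.40) and Hes5 (1.81 ± 0.31) rose. The neural progenitor list was higher in 3 and lower in 1 of 12 measured genes (camera adjusted p = 0.21, adjusted p = 0.46 with an estimated correlation), and the neuron list was higher in 1 and lower in 3 of 11 measured genes (camera adjusted p = 0.012, adjusted p = 0.46 with an estimated correlation). The Hox genes Hoxd3 (2.76 ± 0.42), Hoxa9 (2.22 ± 0.20), Hoxc9 (2.16 ± 0.20), Hoxa10 (3.15 ± 0.25) and Hoxc10 (5.16 ± 0.38) rose. Paralogs 10 to 13 were higher in 3 of 11 measured genes (camera adjusted p = 0.026, adjusted p = 0.46 with an estimated correlation). The growth factor genes Fgf9 (4.76 ± 0.64) and Igf2 (4.68 ± 0.45), the WNT antagonist gene Frzb (4.92 ± 0.76), the WNT effector gene Lef1 (0.98 ± 0.16) and Col3a1 (4.54 ± 0.41) rose. The glucose transporter gene Slc2a1 (−2.24 ± 0.21) and Pdk1 (−2.95 ± 0.41) fell, and hypoxia and glycolysis genes were lower in 5 of 11 measured genes (camera adjusted p = 0.023, adjusted p = 0.46 with an estimated correlation). Adjusted over the list alone, the higher and lower counts were 7 and 0 (presomitic mesoderm), 9 and 0 (Notch) and 1 and 8 (epithelium). They were 0 and 8 (naive pluripotency), 0 and 5 (epiblast) and 3 and 7 (NMP and caudal epiblast). For further lists they were 4 and 2 (neural progenitor), 1 and 4 (neuron), 3 and 0 (Hox paralogs 10 to 13) and 0 and 5 (hypoxia and glycolysis). Called higher by camera too: mesenchyme (3 higher and 0 lower of 11, 3 and 0 adjusted over the list alone, adjusted p = 0.012) and Hox paralogs 1 to 4 (3 higher and 1 lower of 12, 4 and 1 adjusted over the list alone, adjusted p = 0.023). As higher, camera also called Hox paralogs 5 to 9 (6 higher and 1 lower of 14, 6 and 1 adjusted over the list alone, adjusted p = 0.0074). Proliferation (0 higher and 5 lower of 13, 0 and 5 adjusted over the list alone, adjusted p = 0.045) and p53 targets (0 higher and 3 lower of 11, 0 and 3 adjusted over the list alone, adjusted p = 0.026) were lower by camera as well. These lists had adjusted p = 0.34 or more with an estimated correlation. Without a camera call, the counts were 1 higher and 1 lower of 13 (WNT targets, 1 and 1 adjusted over the list alone, adjusted p = 0.94) and 3 higher and 2 lower of 10 (retinoic acid, 3 and 2 adjusted over the list alone, adjusted p = 0.9).

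Of the genes tested, 2376 differed, 1012 higher and 1364 lower. Quantile normalization gave 1057 higher and 1030 lower, and the filter at 20 CPM 885 and 784. Without NMP replicate 1 the count was 1484, without NMP replicate 3 it was 1512, and without Tbxt 48 h replicate 2 it was 709. Adjusted p reached 0.00196 among the 39 named genes past the threshold.

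Cells that kept either reporter were then compared directly, at the same time and in the same medium. Tbxt (2.80 ± 0.36) was higher and Sox2 (−2.56 ± 0.33) lower in Tbxt 48 h than in Sox2 48 h cells; the Sox2 call ended at a pseudocount of 0.25 (adjusted p = 0.0648, range over all alternatives 7.67e-07 to 0.0648). Presomitic mesoderm genes were higher in 8 of 9 measured genes (camera adjusted p = 2.4e-15, adjusted p = 0.018 with an estimated correlation). They included Tbx6 (88.5 ± 43.2 against 0.38 ± 0.54 CPM), Dll1 (5.35 ± 0.48), Dll3 (4.43 ± 0.45) and Lfng (2.74 ± 0.30). Notch pathway genes, with Notch1 (2.47 ± 0.27) among them, were higher in 5 of 10 measured genes (camera adjusted p = 1.5e-07, adjusted p = 0.29 with an estimated correlation). Snai1 (5.21 ± 0.28), Wnt3a (33.3 ± 10.1 against 0 CPM), Cyp26a1 (4.89 ± 0.24), Crabp1 (4.34 ± 0.43) and Lef1 (1.22 ± 0.17) were also higher, as were the sphingosine phosphate receptor gene S1pr3 (26.8 ± 6.37 against 0 CPM) and Rnf213 (5.02 ± 0.43). Neural progenitor genes were lower in 3 of 12 measured genes (camera adjusted p = 0.023, adjusted p = 0.29 with an estimated correlation). Sox3 (−3.75 ± 0.31), Sox1 (−3.17 ± 0.36) and Pou3f2 (−2.79 ± 0.33) were examples. The zinc finger genes Zic2 (−2.56 ± 0.31) and Zic5 (−2.75 ± 0.30) and the peptide hormone gene Apela (−3.77 ± 0.25) were lower. Epithelial genes, such as Epcam (−2.21 ± 0.33) and Cldn6 (−2.60 ± 0.32), were lower in 6 of 10 measured genes (camera adjusted p = 9.4e-07, adjusted p = 0.31 with an estimated correlation). Hoxb1 (3.92 ± 0.42) was higher among Hox paralogs 1 to 4 (1 of 12 measured genes, camera adjusted p = 0.032, adjusted p = 0.54 with an estimated correlation). The NMP and caudal epiblast list was higher in 3 and lower in 1 of 15 measured genes (camera adjusted p = 0.029, adjusted p = 0.31 with an estimated correlation). The higher and lower counts adjusted over the list alone were 8 and 0 (presomitic mesoderm), 8 and 0 (Notch) and 1 and 4 (neural progenitor). Counts of further lists were 0 and 6 (epithelium), 2 and 0 (Hox paralogs 1 to 4) and 5 and 1 (NMP and caudal epiblast). Naive pluripotency (0 higher and 0 lower of 10, 0 and 0 adjusted over the list alone, adjusted p = 0.025) and p53 targets (0 higher and 3 lower of 11, 0 and 3 adjusted over the list alone, adjusted p = 0.00018) were also lower by camera. With an estimated correlation, these lists had adjusted p of at least 0.36. Lists without a camera call held 2 higher and 0 lower of 13 (WNT targets, 2 and 0 adjusted over the list alone, adjusted p = 0.1) and 2 higher and 0 lower of 10 (retinoic acid, 2 and 1 adjusted over the list alone, adjusted p = 0.055).

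This comparison gave 505 genes, 265 higher and 240 lower, but 147 without Sox2 48 h replicate 2 and 132 without Tbxt 48 h replicate 2. More genes were lower than higher without Sox2 48 h replicate 1 (182 and 310), without Tbxt 48 h replicate 1 (146 and 197) and with voom (244 and 288). The same held with array weights (577 and 644), in the fit of these groups alone (505 and 546) and with the 2-fold minimum (195 and 206); each pair gives higher and lower genes. For the 23 named genes past the threshold, adjusted p was at most 0.00231.

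**Figure D2:**
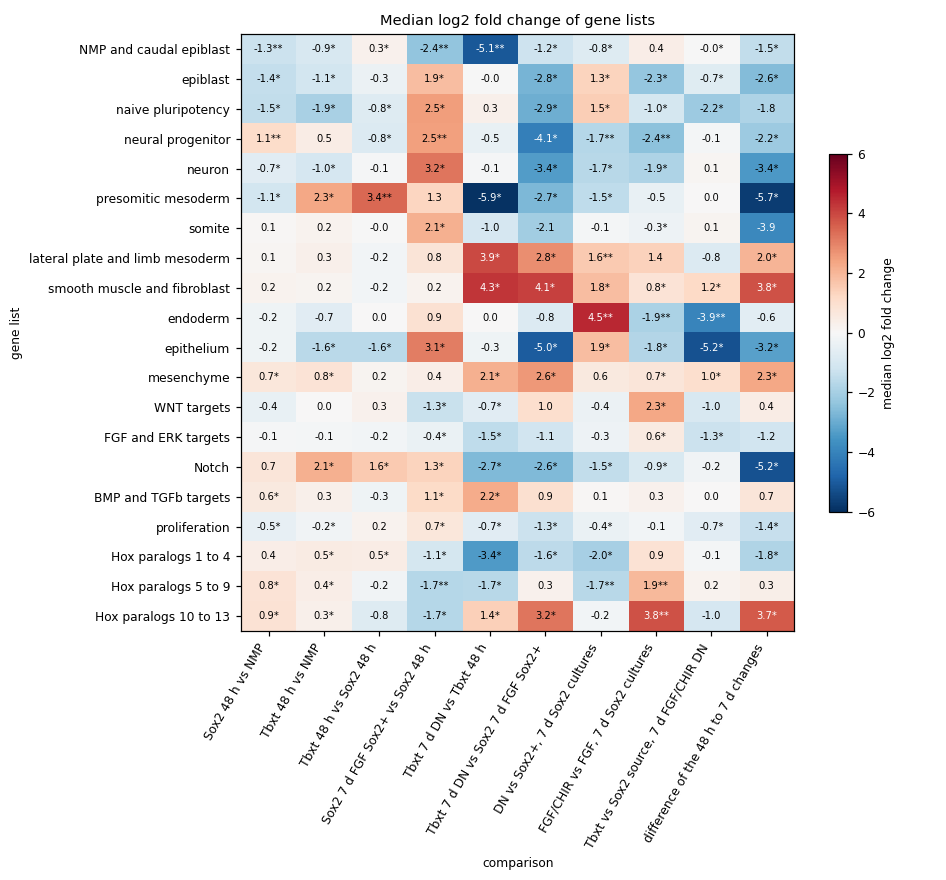
Median log2 fold change of 20 gene lists (rows) in the 10 comparisons (columns), by colour and printed value. An asterisk marks a camera adjusted p under 0.05 with the preset correlation and a second asterisk the same with an estimated correlation. Medians include genes at or near 0 in a group, whose fitted changes depend on the pseudocount of 1.

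From 48 h to 7 d, Sox2-derived cells that stayed Sox2+ in FGF alone were compared with the Sox2 48 h cells, so time and medium changed together. Sox2 differed by 0.83 ± 0.33 (adjusted p = 0.0845), which passed in the fit of these groups alone (adjusted p = 0.0039), at a pseudocount of 4 (0.0101), with array weights (0.0419) and after quantile normalization (0.0466). Over all alternatives it ranged from 0.0039 to 0.388. Tbxt (−2.06 ± 0.36) fell. Neural progenitor genes rose: Fabp7 (6.16 ± 0.44), Pax6 (5.30 ± 0.45), a transcription factor gene of neural progenitors, and Hes5 (5.06 ± 0.34) were higher. The list rose in 9 of 12 measured genes (camera adjusted p = 5.6e-05, adjusted p = 0.04 with an estimated correlation). Without Tbxt 7 d replicate 1, the adjusted p with an estimated correlation was 0.076. Neuronal genes rose in 9 of 11 measured genes, with 1 lower (camera adjusted p = 0.00011, adjusted p = 0.36 with an estimated correlation). They included Elavl3 (5.06 ± 0.52), Dcx (27.6 ± 22.9 against 0 CPM) and Stmn2 (4.30 ± 0.38). The neural transcription factor genes Pou3f3 (5.77 ± 0.42), Msx3 (52.3 ± 28.7 against 0.13 ± 0.18 CPM) and Rfx4 (43.3 ± 7.80 against 0 CPM) and the glycine receptor gene Glra1 (50.3 ± 17.4 against 0 CPM) also rose. The retinoic acid-binding protein genes Crabp1 (7.27 ± 0.43) and Crabp2 (2.45 ± 0.47) and the retinoic acid-degrading enzyme gene Cyp26b1 (53.5 ± 19.9 against 0.11 ± 0.16 CPM) rose. Genes of neural crest, such as Tfap2b (25.6 ± 11.6 against 0.25 ± 0.36 CPM) and Erbb3 (3.16 ± 0.36), were higher in 6 of 11 measured genes, with 1 lower (camera adjusted p = 0.19, adjusted p = 0.51 with an estimated correlation).

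Caudal genes fell over this interval, with Cdx1 (−5.24 ± 0.39), Evx1 (−4.12 ± 0.79), Wnt5b (−3.65 ± 0.34) and Sp5 (−3.41 ± 0.64) as examples. The NMP and caudal epiblast list fell in 12 of 15 measured genes, with 2 higher (camera adjusted p = 5.9e-08, adjusted p = 0.021 with an estimated correlation). WNT target genes were lower in 8 of 13 measured genes (camera adjusted p = 3.8e-07, adjusted p = 0.091 with an estimated correlation), and the FGF pathway gene Il17rd (−1.72 ± 0.25) fell. Hox paralogs 5 to 9 fell in 13 of 14 measured genes (camera adjusted p = 3.8e-14, adjusted p = 0.014 with an estimated correlation), among them Hoxd9 (−3.96 ± 0.69), Hoxc6 (−2.93 ± 0.24) and Hoxa7 (−2.21 ± 0.24). Paralogs 10 to 13 were lower in 4 of 11 measured genes (camera adjusted p = 0.00036, adjusted p = 0.35 with an estimated correlation), with Hoxc10 (−2.98 ± 0.41) and Hoxa10 (−1.87 ± 0.27) as examples, while Hoxa2 (2.17 ± 0.30) rose. The epithelial genes Cdh1 (3.41 ± 0.37), Krt8 (3.53 ± 0.27) and Cldn7 (3.81 ± 0.43) rose. Their list rose in 9 of 10 measured genes (camera adjusted p = 1.5e-07, adjusted p = 0.17 with an estimated correlation). Pluripotency-related genes also rose. Esrrb (3.12 ± 0.52), Nr0b1 (3.03 ± 0.41) and Klf2 (2.88 ± 0.45) were examples of the naive list (7 of 10 measured genes, camera adjusted p = 0.0017, adjusted p = 0.36 with an estimated correlation), and Pou3f1 (4.84 ± 0.48) and Utf1 (2.90 ± 0.45) of the epiblast list (6 of 10 measured genes, camera adjusted p = 0.00073, adjusted p = 0.38 with an estimated correlation). Adjusted over the list alone, the higher and lower counts were 9 and 1 (neural progenitor), 10 and 1 (neuron) and 6 and 1 (neural crest). They were 3 and 12 (NMP and caudal epiblast), 0 and 8 (WNT targets) and 0 and 14 (Hox paralogs 5 to 9). For further lists they were 0 and 5 (Hox paralogs 10 to 13), 9 and 0 (epithelium), 7 and 0 (naive pluripotency) and 6 and 0 (epiblast). Called higher by camera too: somite (5 higher and 0 lower of 8, 5 and 0 adjusted over the list alone, adjusted p = 0.012) and Notch (5 higher and 0 lower of 10, 6 and 1 adjusted over the list alone, adjusted p = 0.038). The camera calls of higher lists included BMP and TGFb targets (7 higher and 0 lower of 11, 7 and 0 adjusted over the list alone, adjusted p = 0.0052) and proliferation (7 higher and 0 lower of 13, 7 and 0 adjusted over the list alone, adjusted p = 0.0017). FGF and ERK targets (0 higher and 2 lower of 12, 0 and 2 adjusted over the list alone, adjusted p = 0.038) and p53 targets (0 higher and 3 lower of 11, 0 and 3 adjusted over the list alone, adjusted p = 0.0023) were lower by camera as well. Hox paralogs 1 to 4 (2 higher and 4 lower of 12, 2 and 6 adjusted over the list alone, adjusted p = 0.0049) was also lower by camera. The lowest adjusted p of these lists with an estimated correlation was 0.15. Without a camera call, the counts were 6 higher and 1 lower of 10 (retinoic acid, 6 and 2 adjusted over the list alone, adjusted p = 0.059).

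Here 3203 genes differed, 2361 higher (73.7%) and 842 lower. Median-of-ratios scaling gave 1720 higher and 1365 lower. Quantile normalization gave 1463 and 1340. The median log2 change of all genes was 0.17 on the deposited scale and 0.01 after median-of-ratios scaling, and the changes given here stand relative to the former. The count was 2096 without Sox2 48 h replicate 1, 1456 without Sox2 48 h replicate 2 and 2117 without the shallow FGF Sox2+ replicate 2, and simulated libraries with this depth gave 60 false calls. The 35 named genes past the threshold had adjusted p of at most 0.00539.

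Tbxt-derived cells that had lost both reporters after 7 d in FGF/CHIR were compared with the Tbxt 48 h cells, with gate and time changing together. Tbxt (−6.86 ± 0.33) and Sox2 (−4.68 ± 0.30) were lower. Genes of connective tissue and limb mesoderm rose: the small leucine-rich proteoglycan genes Lum (200.2 ± 70.4 against 0 CPM) and Dcn (6.34 ± 0.32), the collagen gene Col1a2 (5.53 ± 0.61) and the mesenchymal transcription factor gene Twist1 (6.98 ± 0.37) were higher. The smooth muscle and fibroblast list rose in 9 of 12 measured genes (camera adjusted p = 0.00012, adjusted p = 0.25 with an estimated correlation). Prrx1 (7.58 ± 0.62), Prrx2 (6.52 ± 0.35), Osr1 (5.44 ± 0.49) and Hand2 (4.31 ± 0.34), transcription factor genes of limb and lateral plate mesoderm, rose. The lateral plate and limb list rose in 6 of 9 measured genes (camera adjusted p = 0.0035, adjusted p = 0.11 with an estimated correlation). Cartilage-related genes, such as Pax9 (3.61 ± 0.28), Col11a1 (2.24 ± 0.34) and Col2a1 (1.96 ± 0.24), were higher in 5 of 6 measured genes (camera adjusted p = 0.016, adjusted p = 0.45 with an estimated correlation). The BMP-responsive genes Id1 (3.57 ± 0.26) and Id2 (3.33 ± 0.17) rose. Their list rose in 7 of 11 measured genes (camera adjusted p = 0.0012, adjusted p = 0.3 with an estimated correlation). The retinoic acid-related genes Crabp1 (3.02 ± 0.40) and Cyp26b1 (4.38 ± 0.39) rose and Cyp26a1 (0 against 64.1 ± 4.07 CPM) fell. Cdo1 (7.88 ± 0.41), Bcl11a (7.24 ± 0.37), Runx1t1 (7.22 ± 0.35) and Pcdh10 (7.14 ± 0.64) were among the largest rises.

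Presomitic mesoderm genes fell in 8 of 9 measured genes (camera adjusted p = 1.7e-06, adjusted p = 0.11 with an estimated correlation). Examples were Dll1 (−7.08 ± 0.44), Hes7 (−6.93 ± 0.30), Tbx6 (0.25 ± 0.05 against 88.5 ± 43.2 CPM) and Cited1 (−6.05 ± 0.33). Notch pathway genes fell in 8 of 10 measured genes (camera adjusted p = 2.9e-05, adjusted p = 0.25 with an estimated correlation), with Nrarp (−5.87 ± 0.34) and Notch1 (−3.49 ± 0.25) as examples. The NMP and caudal epiblast list fell in 14 of 15 measured genes (camera adjusted p = 7.9e-10, adjusted p = 0.021 with an estimated correlation), with Cdx2 (−7.83 ± 0.20), Sp8 (−5.87 ± 0.28) and Fgf8 (−5.86 ± 0.39) among the genes. Without FGF Sox2+ replicate 2, the adjusted p with an estimated correlation was 0.086. Lin28a (−7.19 ± 0.15), an RNA-binding protein gene of early embryonic cells, Foxb1 (0.10 ± 0.17 against 196 ± 13.8 CPM), Lmo2 (−7.34 ± 0.34) and Cxcr4 (−7.26 ± 0.25) also fell. FGF and ERK target genes were lower in 9 of 12 measured genes (camera adjusted p = 0.0048, adjusted p = 0.45 with an estimated correlation), with Dusp4 (−3.06 ± 0.35), Spry4 (−3.17 ± 0.72) and Etv5 (−2.80 ± 0.59) as examples. Tbxt 7 d replicate 1 stood apart from replicates 2 and 3 in FGF and, both ways, in WNT target genes (5 lower and 2 higher of 13 by over 2-fold). Dusp6 was 104, 5.94 and 4.74 CPM in replicates 1, 2 and 3, and Spry1 was 47.2, 1.58 and 1.05 CPM. Of WNT targets, Axin2 was 93.5, 556 and 546 CPM, but Dkk1 was 66.7, 5.74 and 2.37 CPM. Proliferation genes fell in 9 of 13 measured genes (camera adjusted p = 0.0006, adjusted p = 0.3 with an estimated correlation), among them Ccne1 (−2.38 ± 0.30), Pcna (−1.44 ± 0.18) and Mcm2 (−1.16 ± 0.16). Hox paralogs 1 to 4 fell in 12 of 12 measured genes (camera adjusted p = 2.1e-07, adjusted p = 0.21 with an estimated correlation), with Hoxb1 (0.27 ± 0.26 against 104 ± 0.21 CPM) and Hoxd4 (−3.91 ± 0.74) as examples. Hoxc6 (−2.87 ± 0.22) and Hoxb8 (−2.67 ± 0.33) fell among paralogs 5 to 9 (2 higher and 10 lower of 14 measured genes, camera adjusted p = 0.0036, adjusted p = 0.25 with an estimated correlation). Hoxa10 (2.99 ± 0.25), Hoxa11 (4.81 ± 0.39) and Hoxd11 (5.49 ± 0.58) rose. Hox paralogs 10 to 13 rose in 5 of 11 measured genes (camera adjusted p = 0.037, adjusted p = 0.45 with an estimated correlation). The higher and lower counts adjusted over the list alone were 9 and 0 (smooth muscle and fibroblast), 6 and 0 (lateral plate and limb mesoderm) and 6 and 0 (sclerotome and cartilage). Counts of further lists were 7 and 0 (BMP and TGFb targets), 0 and 8 (presomitic mesoderm) and 0 and 9 (Notch). They were 0 and 14 (NMP and caudal epiblast), 0 and 9 (FGF and ERK targets) and 0 and 9 (proliferation). For further lists they were 0 and 12 (Hox paralogs 1 to 4), 2 and 10 (Hox paralogs 5 to 9) and 5 and 0 (Hox paralogs 10 to 13). Called higher by camera too: mesenchyme (6 higher and 0 lower of 11, 6 and 1 adjusted over the list alone, adjusted p = 0.012). As lower, camera also called WNT targets (1 higher and 6 lower of 13, 1 and 6 adjusted over the list alone, adjusted p = 0.041) and p53 targets (1 higher and 7 lower of 11, 1 and 7 adjusted over the list alone, adjusted p = 0.033). These lists had adjusted p = 0.45 or more with an estimated correlation. Lists without a camera call held 7 higher and 1 lower of 10 (retinoic acid, 7 and 1 adjusted over the list alone, adjusted p = 0.099).

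In total, 7014 genes differed, 3969 higher and 3045 lower. Quantile normalization gave 2954 and 3751. The 48 named genes past the threshold had adjusted p of at most 0.00357.

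**Figure D3:**
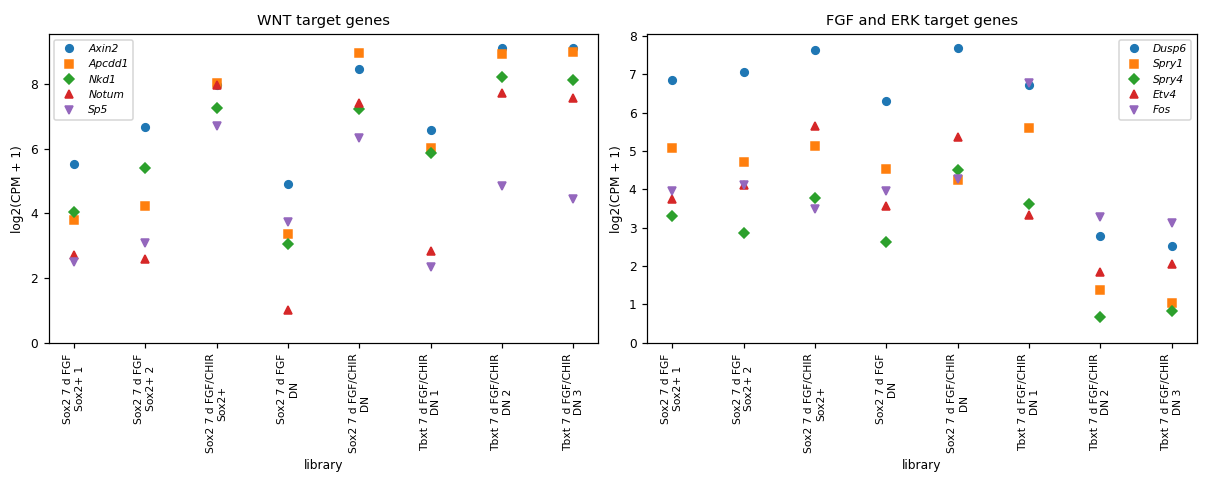
Levels of 5 WNT target genes (left) and 5 FGF and ERK target genes (right) in each 7 d library, as log2(CPM + 1). In Tbxt 7 d replicate 1, Notum was 6.11 CPM against 211 and 189.6 CPM in replicates 2 and 3, while Fos was 107 CPM against 8.71 and 7.64 CPM.

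The replicated 7 d groups, Tbxt 7 d cells and FGF Sox2+ cells, differed in source, gate and medium at once. Sox2 (−8.06 ± 0.30) was lower in Tbxt 7 d cells, and Tbxt was 1.03 ± 0.94 CPM against 6.82 ± 2.74 CPM (adjusted p = 0.000329). Neural genes were lower: Fabp7 (−8.29 ± 0.40), Sox1 (0 against 146 ± 47.2 CPM), Hes5 (0 against 146 ± 73.1 CPM) and Pou3f2 (0.19 ± 0.34 against 135 ± 37.4 CPM) were examples. The neural progenitor list was lower in 8 of 12 measured genes, with 1 higher (camera adjusted p = 0.00024, adjusted p = 0.18 with an estimated correlation). The neuron list was lower in 10 of 11 measured genes (camera adjusted p = 5e-05, adjusted p = 0.26 with an estimated correlation), with Elavl3 (0.07 ± 0.11 against 64.2 ± 52.6 CPM) and Elavl4 (−5.28 ± 0.39) as examples. Every measured epithelial gene was lower (10 of 10, camera adjusted p = 6e-08, adjusted p = 0.18 with an estimated correlation). Among them were Krt8 (0.23 ± 0.20 against 117 ± 21.2 CPM), Krt18 (−5.77 ± 0.36), Cdh1 (0.15 ± 0.14 against 66.4 ± 35.5 CPM) and Cldn6 (0 against 42.9 ± 21.7 CPM). Pou3f1 (−6.52 ± 0.44), Utf1 (0.09 ± 0.15 against 33.4 ± 24.2 CPM) and Dnmt3b (−3.54 ± 0.25) of the epiblast list were lower (6 of 10 measured genes, camera adjusted p = 0.00024, adjusted p = 0.32 with an estimated correlation). Lin28a (−6.59 ± 0.15) was lower too.

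Mesenchymal genes were higher in Tbxt 7 d cells: Col3a1 (6.78 ± 0.41), Lum (200.2 ± 70.4 against 0.63 ± 0.89 CPM), Dcn (5.69 ± 0.32) and Twist1 (5.39 ± 0.37) were examples. The smooth muscle and fibroblast list was higher in 10 of 12 measured genes (camera adjusted p = 7.7e-07, adjusted p = 0.18 with an estimated correlation). Prrx1 (6.80 ± 0.62), Prrx2 (5.32 ± 0.35), Hand2 (63.8 ± 17.3 against 0.32 ± 0.45 CPM) and Osr1 (64.2 ± 25.4 against 1.36 ± 1.62 CPM) were higher and Hand1 (−5.12 ± 0.43) was lower in the lateral plate and limb list (5 higher and 1 lower of 9 measured genes, camera adjusted p = 0.017, adjusted p = 0.18 with an estimated correlation). The mesenchyme list was higher in 8 of 11 measured genes (camera adjusted p = 0.00024, adjusted p = 0.26 with an estimated correlation), with Snai2 (4.51 ± 0.53) as an example. The secreted WNT pathway gene Dkk2 (145 ± 25.4 against 0.32 ± 0.45 CPM) and the feedback gene Nkd2 (6.80 ± 0.33) were higher. Hoxa9 (2.69 ± 0.20), Hoxa5 (2.24 ± 0.20), Hoxa10 (4.59 ± 0.25) and Hoxa11 (71.7 ± 31.3 against 0.21 ± 0.30 CPM) were higher, and Hoxb1 (0.27 ± 0.26 against 13.2 ± 9.84 CPM), Hoxb2 (−4.18 ± 0.29) and Hoxa2 (−3.10 ± 0.28) were lower. Paralogs 10 to 13 were higher in 6 of 11 measured genes (camera adjusted p = 0.00045, adjusted p = 0.26 with an estimated correlation). The paralogs 1 to 4 were lower in 8 of 12 measured genes (camera adjusted p = 0.00089, adjusted p = 0.26 with an estimated correlation). Proliferation genes were lower in 12 of 13 measured genes (camera adjusted p = 4e-06, adjusted p = 0.18 with an estimated correlation), among them Ccne1 (−2.33 ± 0.30), Ccnb1 (−1.72 ± 0.14) and Mcm5 (−1.54 ± 0.14). Adjusted over the list alone, the higher and lower counts were 1 and 8 (neural progenitor), 0 and 10 (neuron) and 0 and 10 (epithelium). Counts of further lists were 0 and 7 (epiblast), 10 and 0 (smooth muscle and fibroblast) and 5 and 1 (lateral plate and limb mesoderm). They were 8 and 0 (mesenchyme), 7 and 0 (Hox paralogs 10 to 13), 0 and 9 (Hox paralogs 1 to 4) and 0 and 12 (proliferation). NMP and caudal epiblast (2 higher and 9 lower of 15, 2 and 9 adjusted over the list alone, adjusted p = 0.017) and naive pluripotency (1 higher and 7 lower of 10, 1 and 7 adjusted over the list alone, adjusted p = 0.0083) were lower by camera as well. Presomitic mesoderm (0 higher and 5 lower of 9, 0 and 5 adjusted over the list alone, adjusted p = 0.017) and Notch (1 higher and 8 lower of 10, 1 and 8 adjusted over the list alone, adjusted p = 0.00088) were also lower by camera. Called lower by camera too: p53 targets (0 higher and 7 lower of 11, 0 and 7 adjusted over the list alone, adjusted p = 0.043). With an estimated correlation, these lists had adjusted p of at least 0.26. Without a camera call, the counts were 4 higher and 3 lower of 14 (Hox paralogs 5 to 9, 4 and 3 adjusted over the list alone, adjusted p = 0.31).

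The groups differed in 6161 genes, 2729 higher and 3432 lower, and simulated libraries of these depths gave 70 false calls. Adjusted p was at most 0.000329 for the 38 named genes past the threshold.

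Within the 7 d Sox2-derived cultures, DN cells were compared with Sox2+ cells, averaged over FGF and FGF/CHIR. Levels of DN against Sox2+ cells are given for FGF, then FGF/CHIR. Sox2 (−4.37 ± 0.30) was lower in DN cells, and Tbxt differed by −0.72 ± 0.34 (adjusted p = 0.174). Endoderm genes were higher in DN cells in 8 of 8 measured genes (camera adjusted p = 7.7e-15, adjusted p = 0.0019 with an estimated correlation). They included the endoderm transcription factor genes Gata6 (6.59 ± 0.66), Sox17 (228 against 2.09 ± 2.36 and 37.9 against 0.10 CPM), Gata4 (4.97 ± 0.41) and Foxa2 (4.16 ± 0.31), and Spink1 (105 against 0.32 ± 0.45 and 6.40 against 0.10 CPM). Sox7 (174 against 0.73 ± 0.74 and 22.6 against 0 CPM), Cubn (95.2 against 0.16 ± 0.23 and 164 against 0.15 CPM), Foxq1 (5.96 ± 0.47), Ctsh (113 against 1.46 ± 1.47 and 61.5 against 0.31 CPM) and Fxyd3 (315 against 1.78 ± 1.02 and 19.9 against 0.10 CPM) were among the largest rises. The epithelial genes Krt8 (2.53 ± 0.25), Krt18 (2.34 ± 0.37), Cdh1 (2.40 ± 0.35) and Cldn7 (2.21 ± 0.40) were higher. Their list was higher in 8 of 10 measured genes (camera adjusted p = 2.5e-09, adjusted p = 0.096 with an estimated correlation). Pdgfra (4.51 ± 0.36) and Bmp4 (1.66 ± 0.32) were higher. The lateral plate and limb list, which also holds Gata4 and Gata6, was higher in 5 of 9 measured genes (camera adjusted p = 1.1e-05, adjusted p = 0.014 with an estimated correlation). Pou5f1 (3.39 ± 0.42) and Klf4 (3.45 ± 0.44) were higher. The naive pluripotency list was higher in 4 and lower in 1 of 10 measured genes (camera adjusted p = 0.0018, adjusted p = 0.37 with an estimated correlation).

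Neural genes were lower in DN cells: Fabp7 (24.8 against 429 ± 201 and 0 against 21.4 CPM), Pou3f2 (3.51 against 135 ± 37.4 and 0.69 against 7.50 CPM), Hes5 (6.60 against 146 ± 73.1 and 0.23 against 5.65 CPM) and Sox1 (14.7 against 146 ± 47.2 and 0.23 against 5.55 CPM) fell. The neural progenitor list was lower in 8 of 12 measured genes (camera adjusted p = 1.3e-07, adjusted p = 0.014 with an estimated correlation). The neuron list was lower in 7 of 11 measured genes (camera adjusted p = 0.00031, adjusted p = 0.37 with an estimated correlation), with Map2 (−2.53 ± 0.43) as an example. Notch pathway genes were lower in 8 of 10 measured genes (camera adjusted p = 2.7e-05, adjusted p = 0.22 with an estimated correlation), with Dll1 (−3.08 ± 0.45), Dll3 (−2.54 ± 0.42) and Nrarp (−1.90 ± 0.35) as examples. Cdx2 (−3.04 ± 0.20) and the chemokine receptor gene Cxcr4 (−4.07 ± 0.25) were lower. Hox paralogs 1 to 4 were lower in 9 of 12 measured genes (camera adjusted p = 1.8e-08, adjusted p = 0.096 with an estimated correlation). Paralogs 5 to 9 were lower in 12 of 14 measured genes (camera adjusted p = 1.1e-09, adjusted p = 0.014 with an estimated correlation). Examples were Hoxc4 (−2.51 ± 0.17), Hoxb2 (−2.33 ± 0.30), Hoxc6 (−2.15 ± 0.23), Hoxa7 (−2.12 ± 0.23) and Hoxb7 (−2.05 ± 0.18). The higher and lower counts adjusted over the list alone were 8 and 0 (endoderm), 10 and 0 (epithelium) and 6 and 0 (lateral plate and limb mesoderm). For further lists they were 7 and 2 (naive pluripotency), 0 and 8 (neural progenitor) and 0 and 7 (neuron). Counts of further lists were 0 and 8 (Notch), 0 and 10 (Hox paralogs 1 to 4) and 0 and 12 (Hox paralogs 5 to 9). The camera calls of higher lists included epiblast (2 higher and 0 lower of 10, 5 and 0 adjusted over the list alone, adjusted p = 0.00031) and smooth muscle and fibroblast (6 higher and 0 lower of 12, 7 and 0 adjusted over the list alone, adjusted p = 1.3e-07). NMP and caudal epiblast (1 higher and 7 lower of 15, 1 and 7 adjusted over the list alone, adjusted p = 0.02) and presomitic mesoderm (2 higher and 5 lower of 9, 2 and 6 adjusted over the list alone, adjusted p = 0.044) were lower by camera as well. Proliferation (0 higher and 5 lower of 13, 0 and 6 adjusted over the list alone, adjusted p = 0.0011) was also lower by camera. The lowest adjusted p of these lists with an estimated correlation was 0.096.

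The comparison gave 1826 genes, 921 higher and 905 lower, and median-of-ratios scaling gave 1206 higher and 611 lower. The median log2 change of all genes was −0.11 on the deposited scale and 0.01 after that scaling, and the changes given stand relative to the former. More genes were lower than higher at a pseudocount of 0.25 (836 higher and 864 lower), with the filter at 20 CPM (690 and 695), with array weights (1743 and 2289) and without FGF Sox2+ replicate 1 (1110 and 1156). Both DN groups and FGF/CHIR Sox2+ cells held 1 library, whose spread was taken from the replicated groups. Adjusted p was at most 0.00442 for the 34 named genes past the threshold.

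Sox2-derived 7 d cultures in FGF/CHIR were compared with those in FGF, averaged over gates. CHIR may rest on 1 culture, as both FGF/CHIR libraries may share it. Levels with CHIR against without are given for Sox2+, then DN cells. Sox2 (−1.64 ± 0.30) was lower with CHIR, a call that ended at a pseudocount of 0.25 (adjusted p = 0.0989, range over all alternatives 8.38e-06 to 0.0989). Tbxt (−1.10 ± 0.34) was lower, but not without FGF Sox2+ replicate 2 (adjusted p = 0.101), at pseudocounts of 0.25 or 4, without the filter, with voom or in the fit of these groups alone. Its adjusted p ranged over all alternatives from 0.0173 to 0.199. WNT target genes were higher in 9 of 13 measured genes, with 1 lower (camera adjusted p = 1.1e-06, adjusted p = 0.089 with an estimated correlation). Examples were Apcdd1 (4.80 ± 0.76), Nkd1 (3.36 ± 0.66) and Sp5 (3.26 ± 0.60), and the WNT feedback gene Nkd2 (5.35 ± 0.34) was higher. Posterior Hox genes were higher in FGF/CHIR: Hoxd11 (6.08 ± 0.60), Hoxc11 (75.4 against 0.84 ± 0.59 and 28.0 against 0.41 CPM) and Hoxd10 (4.08 ± 0.49) were examples. Paralogs 10 to 13 were higher in 10 of 11 measured genes (camera adjusted p = 3.5e-12, adjusted p = 0.049 with an estimated correlation). Paralogs 5 to 9 were higher in 13 of 14 measured genes (camera adjusted p = 3.8e-14, adjusted p = 0.014 with an estimated correlation), with Hoxa5 (2.89 ± 0.20), Hoxb9 (2.55 ± 0.31) and Hoxd8 (2.55 ± 0.60) as examples. Without FGF Sox2+ replicate 2, the adjusted p with an estimated correlation was 0.074 for paralogs 10 to 13, and without Tbxt 7 d replicate 1 it was 0.051 for paralogs 5 to 9. Hoxd1 (4.33 ± 0.37) was higher and Hoxb1 (0.82 against 13.2 ± 9.84 and 0.23 against 5.16 CPM) and Hoxa2 (−1.55 ± 0.28) were lower. The NMP and caudal epiblast list was higher in 7 and lower in 5 of 15 measured genes (camera adjusted p = 0.46, adjusted p = 0.63 with an estimated correlation), with Evx1 (3.04 ± 0.74) and Wnt5b (2.86 ± 0.32) among the higher genes. The mesenchymal genes Twist1 (3.52 ± 0.38), Pdgfrb (2.00 ± 0.28) and Hand2 (2.57 against 0.32 ± 0.45 and 34.7 against 1.24 CPM) were higher. The mesenchyme list was higher in 3 of 11 measured genes (camera adjusted p = 0.00016, adjusted p = 0.25 with an estimated correlation).

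Neural genes were lower with CHIR: Fabp7 (21.4 against 429 ± 201 and 0 against 24.8 CPM), Sox1 (5.55 against 146 ± 47.2 and 0.23 against 14.7 CPM), Hes5 (5.65 against 146 ± 73.1 and 0.23 against 6.60 CPM) and Pax6 (0.21 against 82.1 ± 18.7 and 0.46 against 5.78 CPM) were examples. The neural progenitor list was lower in 8 of 12 measured genes, with 2 higher (camera adjusted p = 5e-05, adjusted p = 0.041 with an estimated correlation). Without Tbxt 7 d replicate 1, its adjusted p with an estimated correlation was 0.093. The neuron list was lower in 7 of 11 measured genes, with 1 higher (camera adjusted p = 0.00017, adjusted p = 0.36 with an estimated correlation), with Stmn2 (−4.33 ± 0.36) and Elavl3 (1.03 against 64.2 ± 52.6 and 0.46 against 7.43 CPM) as examples. Epiblast genes were lower in 9 of 10 measured genes (camera adjusted p = 4.3e-08, adjusted p = 0.21 with an estimated correlation), with Pou3f1 (−4.89 ± 0.45) as an example. Epithelial genes were lower in 7 of 10 measured genes (camera adjusted p = 1.7e-07, adjusted p = 0.18 with an estimated correlation). They included Krt8 (−2.54 ± 0.25), Epcam (−1.87 ± 0.31) and Esrp1 (−2.32 ± 0.30). The endoderm list was lower with CHIR in 6 of 8 measured genes, such as Foxa2 (−2.26 ± 0.31) and Gata4 (−1.94 ± 0.41). The camera adjusted p was 0.00016, and 0.041 with an estimated correlation (0.051 without Tbxt 7 d replicate 1). Visceral genes (below), DN over Sox2+, had medians of 2.55 with CHIR and 2.39 without. Fst (−4.87 ± 0.33) and Hand1 (−4.33 ± 0.44) were also lower. Adjusted over the list alone, the higher and lower counts were 9 and 1 (WNT targets), 11 and 0 (Hox paralogs 10 to 13) and 13 and 0 (Hox paralogs 5 to 9). They were 7 and 5 (NMP and caudal epiblast), 5 and 0 (mesenchyme) and 2 and 8 (neural progenitor). For further lists they were 1 and 8 (neuron), 0 and 10 (epiblast), 0 and 9 (epithelium) and 0 and 6 (endoderm). Called higher by camera too: smooth muscle and fibroblast (4 higher and 0 lower of 12, 5 and 1 adjusted over the list alone, adjusted p = 0.0039) and FGF and ERK targets (2 higher and 0 lower of 12, 2 and 0 adjusted over the list alone, adjusted p = 0.048). As higher, camera also called mitochondrial transcripts (0 higher and 0 lower of 13, 0 and 0 adjusted over the list alone, adjusted p = 0.027). Naive pluripotency (0 higher and 3 lower of 10, 0 and 5 adjusted over the list alone, adjusted p = 0.0075) and somite (0 higher and 3 lower of 8, 0 and 3 adjusted over the list alone, adjusted p = 0.048) were lower by camera as well. Notch (1 higher and 4 lower of 10, 2 and 6 adjusted over the list alone, adjusted p = 0.038) was also lower by camera. These lists had adjusted p = 0.21 or more with an estimated correlation. Lists without a camera call held 4 higher and 2 lower of 12 (Hox paralogs 1 to 4, 7 and 2 adjusted over the list alone, adjusted p = 0.13) and 4 higher and 2 lower of 9 (lateral plate and limb mesoderm, 5 and 2 adjusted over the list alone, adjusted p = 0.14).

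Here 1786 genes differed, 769 higher and 1017 lower, with 1 library in 3 of the 4 groups. Named genes past the threshold numbered 34, with adjusted p of at most 0.0465.

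**Figure D4:**
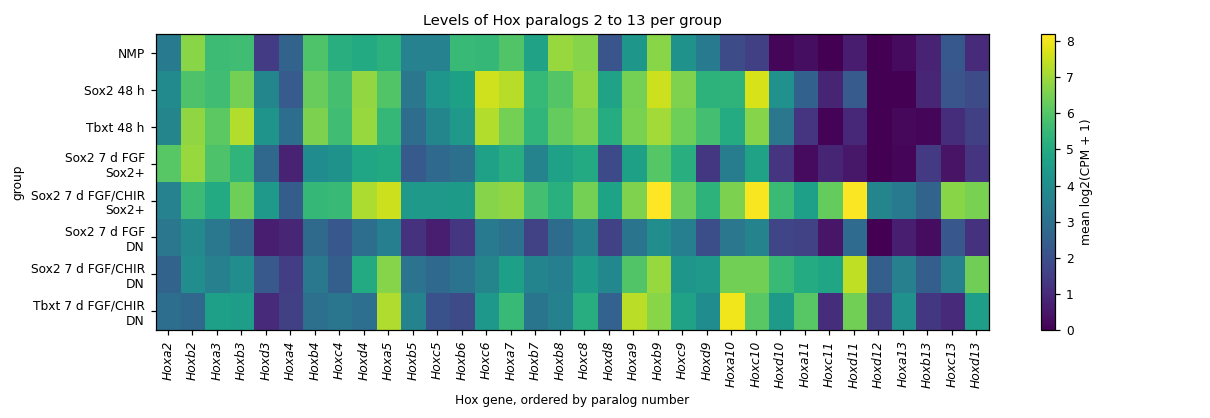
Mean log2(CPM + 1) of the measured genes of Hox paralogs 2 to 13 (columns, by paralog number) in the 8 groups (rows). Hoxd11 was 281 and 169 CPM in FGF/CHIR Sox2+ and DN cells, against 0.53 ± 0.75 and 6.29 CPM in FGF Sox2+ and DN cells.

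At the same time, medium and gate, Tbxt 7 d cells were compared with FGF/CHIR DN cells of Sox2-derived cultures, 3 libraries against 1. Sox2 (−2.05 ± 0.38) was lower in Tbxt 7 d cells; this call ended in the fit of these groups alone (adjusted p = 0.127, range over all alternatives 5.79e-07 to 0.127). Tbxt was 1.03 ± 0.94 CPM in Tbxt 7 d and 1.14 CPM in FGF/CHIR DN cells. Endoderm genes were lower in Tbxt 7 d cells in 8 of 8 measured genes (camera adjusted p = 1.9e-10, adjusted p = 0.0065 with an estimated correlation). Examples were Cldn6 (0 against 41.4 CPM), Sox17 (0 against 37.9 CPM), Foxa2 (0.18 ± 0.16 against 10.5 CPM) and Gata4 (−3.75 ± 0.51). As above, the filter favours the 8 of 8. Every measured epithelial gene was lower (10 of 10, camera adjusted p = 3.9e-15, adjusted p = 0.093 with an estimated correlation). They included Krt8 (0.23 ± 0.20 against 115 CPM), Krt18 (−6.08 ± 0.46), Cdh1 (0.15 ± 0.14 against 101 CPM) and Cldn4 (0.09 ± 0.15 against 49.8 CPM). The pluripotency-related genes Dppa5a (0.03 ± 0.06 against 264 CPM), Klf5 (−5.12 ± 0.49), Zfp42 (0.20 ± 0.20 against 16.1 CPM) and Pou5f1 (−4.74 ± 0.52) were lower. The naive pluripotency list was lower in 6 of 10 measured genes (camera adjusted p = 4.4e-05, adjusted p = 0.41 with an estimated correlation). Cubn (−6.50 ± 0.46), Srgn (0.36 ± 0.4 against 221.5 CPM), Foxq1 (−6.48 ± 0.57), Fabp3 (−7.11 ± 0.34) and the water channel gene Aqp8 (0 against 68.8 CPM) were among the largest falls.

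Higher in Tbxt 7 d cells were the limb transcription factor genes Shox2 (5.52 ± 0.62) and Osr1 (64.2 ± 25.4 against 0.46 CPM), the matrix genes Dcn (2.94 ± 0.41) and Col1a2 (3.98 ± 0.77), the chemokine receptor gene Ackr3 (3.93 ± 0.38) and the cartilage-related gene Pax9 (2.08 ± 0.35). The lateral plate and limb list was higher in 2 and lower in 3 of 9 measured genes (camera adjusted p = 0.61, adjusted p = 0.74 with an estimated correlation). The smooth muscle and fibroblast list was higher in 3 of 12 measured genes (camera adjusted p = 0.01, adjusted p = 0.5 with an estimated correlation), and its camera adjusted p was 0.15 without Tbxt 7 d replicate 1. Hoxa10 (1.57 ± 0.31) was higher, and Hoxd1 (−3.37 ± 0.46) and Nkx1-2 (−4.93 ± 0.35) were lower. Proliferation genes were lower in 9 of 13 measured genes (camera adjusted p = 3.2e-05, adjusted p = 0.31 with an estimated correlation). The higher and lower counts adjusted over the list alone were 0 and 8 (endoderm), 0 and 10 (epithelium) and 0 and 7 (naive pluripotency). Counts of further lists were 2 and 3 (lateral plate and limb mesoderm), 5 and 0 (smooth muscle and fibroblast) and 0 and 11 (proliferation). Called higher by camera too: mesenchyme (2 higher and 0 lower of 11, 3 and 0 adjusted over the list alone, adjusted p = 0.034). The camera calls of lower lists included NMP and caudal epiblast (0 higher and 5 lower of 15, 0 and 6 adjusted over the list alone, adjusted p = 0.0072) and epiblast (0 higher and 4 lower of 10, 0 and 4 adjusted over the list alone, adjusted p = 0.003). FGF and ERK targets (0 higher and 2 lower of 12, 0 and 6 adjusted over the list alone, adjusted p = 0.0012) and p53 targets (0 higher and 4 lower of 11, 0 and 5 adjusted over the list alone, adjusted p = 0.0057) were lower by camera as well. With an estimated correlation, these lists had adjusted p of at least 0.31. Without a camera call, the counts were 1 higher and 3 lower of 12 (Hox paralogs 1 to 4, 2 and 3 adjusted over the list alone, adjusted p = 0.39), 2 higher and 0 lower of 14 (Hox paralogs 5 to 9, 2 and 0 adjusted over the list alone, adjusted p = 0.57), 1 higher and 2 lower of 11 (Hox paralogs 10 to 13, 1 and 2 adjusted over the list alone, adjusted p = 0.39) and 2 higher and 0 lower of 6 (sclerotome and cartilage, 2 and 0 adjusted over the list alone, adjusted p = 0.11).

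The count was 2167 genes, 1020 higher and 1147 lower, and 1378 without Tbxt 7 d replicate 3. The fit of these groups alone gave 558 genes, 307 higher and 251 lower. A pseudocount of 4 gave 1147 higher and 1120 lower, and the 2-fold minimum 768 and 691. The 27 named genes past the threshold had adjusted p of at most 0.00785.

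The changes from 48 h to 7 d were finally set against each other, as the change in Tbxt-derived cells (to DN cells in FGF/CHIR) minus that in Sox2-derived cells (to Sox2+ cells in FGF), so lineage, gate and medium differed together. A positive value means a more positive change in Tbxt-derived cells. The difference was −5.50 ± 0.44 for Sox2 and −4.80 ± 0.48 for Tbxt. Mesenchymal and limb genes had positive differences, among them Col3a1 (7.45 ± 0.60), Lum (7.01 ± 0.55), Twist1 (6.89 ± 0.55), Dcn (6.02 ± 0.48), Prrx1 (7.27 ± 0.92), Hand2 (5.66 ± 0.50) and Shox2 (7.17 ± 0.73). The smooth muscle and fibroblast list had positive differences in 7 of 12 measured genes (camera adjusted p = 1.2e-06, adjusted p = 0.12 with an estimated correlation). The skeletal and mesenchymal transcription factor gene Runx2 (8.12 ± 0.96) and the glycosyltransferase gene Gxylt2 (7.30 ± 0.32) also had positive differences. Hoxa10 (4.87 ± 0.37), Hoxa11 (7.08 ± 0.58), Hoxa9 (2.62 ± 0.30) and Hoxa5 (2.75 ± 0.29) had positive and Hoxb1 (−7.22 ± 0.56) and Hoxb2 (−5.12 ± 0.44) negative differences. Paralogs 10 to 13 had positive differences in 6 of 11 measured genes (camera adjusted p = 5.5e-05, adjusted p = 0.19 with an estimated correlation).

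Presomitic mesoderm and Notch genes had negative differences, with Dll1 (−10.25 ± 0.65), Dll3 (−7.83 ± 0.61), Cited1 (−7.17 ± 0.49), Hes5 (−7.96 ± 0.47) and Nrarp (−6.96 ± 0.51) as examples. The presomitic mesoderm list was lower in 8 of 9 measured genes (camera adjusted p = 4e-08, adjusted p = 0.11 with an estimated correlation). The Notch list was lower in 8 of 10 measured genes (camera adjusted p = 5.7e-06, adjusted p = 0.18 with an estimated correlation). Neural genes had negative differences, among them Fabp7 (−9.49 ± 0.59), Pax6 (−5.68 ± 0.61), Elavl3 (−5.52 ± 0.71) and Stmn2 (−3.65 ± 0.52). The neuron list was lower in 9 of 11 measured genes (camera adjusted p = 0.00019, adjusted p = 0.37 with an estimated correlation). Every measured epithelial gene had a negative difference (10 of 10, camera adjusted p = 1.2e-06, adjusted p = 0.18 with an estimated correlation), with Krt8 (−5.50 ± 0.36) and Krt18 (−3.61 ± 0.54) as examples. Cyp26a1 (−7.56 ± 0.33), Wnt3a (−8.09 ± 0.41) and Cxcr4 (−7.63 ± 0.37) also had negative differences. Proliferation genes were lower in 12 of 13 measured genes (camera adjusted p = 5.4e-07, adjusted p = 0.12 with an estimated correlation). Adjusted over the list alone, the higher and lower counts were 9 and 0 (smooth muscle and fibroblast), 6 and 0 (Hox paralogs 10 to 13) and 0 and 9 (presomitic mesoderm). They were 0 and 8 (Notch), 0 and 9 (neuron), 0 and 10 (epithelium) and 0 and 13 (proliferation). Lateral plate and limb mesoderm (5 higher and 1 lower of 9, 5 and 1 adjusted over the list alone, adjusted p = 0.0091) and mesenchyme (6 higher and 1 lower of 11, 6 and 1 adjusted over the list alone, adjusted p = 0.013) were also higher by camera. Called lower by camera too: NMP and caudal epiblast (1 higher and 8 lower of 15, 1 and 8 adjusted over the list alone, adjusted p = 0.00077) and epiblast (0 higher and 7 lower of 10, 0 and 7 adjusted over the list alone, adjusted p = 0.00064). As lower, camera also called neural progenitor (1 higher and 7 lower of 12, 1 and 7 adjusted over the list alone, adjusted p = 0.0026) and Hox paralogs 1 to 4 (0 higher and 8 lower of 12, 0 and 9 adjusted over the list alone, adjusted p = 0.00015). The lowest adjusted p of these lists with an estimated correlation was 0.12. Lists without a camera call held 4 higher and 0 lower of 14 (Hox paralogs 5 to 9, 5 and 1 adjusted over the list alone, adjusted p = 0.084).

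The difference passed the test in 4346 genes, 1834 positive and 2512 negative, and in 2595 genes without Tbxt 48 h replicate 2. In 761 genes the difference and both of its changes passed, and in 345 of these the changes went opposite ways, 93 rising in Tbxt-derived and falling in Sox2-derived cells and 252 the reverse. The 31 named genes past the threshold had adjusted p of at most 0.000405. Of these genes, Lum, Runx2, Hand2, Hoxa11, Hoxb1, Hes5, Elavl3, Krt8, Cyp26a1 and Wnt3a had a group with at most 3 reads, and their differences depend on the pseudocount of 1.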

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

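The genes below were singled out because the test of the difference between the 48 h to 7 d changes passed and the changes went opposite ways. Genes that rose in Tbxt-derived and fell in Sox2-derived cells were Col3a1 (difference in log2 change 7.45 ± 0.60), Gxylt2 (7.30 ± 0.32), Hand2 (5.66 ± 0.50), Hoxa5 (2.75 ± 0.29), Hoxa9 (2.62 ± 0.30), Hoxa10 (4.87 ± 0.37) and Hoxa11 (7.08 ± 0.58). Genes that fell in Tbxt-derived and rose in Sox2-derived cells were Cited1 (−7.17 ± 0.49), Cyp26a1 (−7.56 ± 0.33), Dll1 (−10.25 ± 0.65), Dll3 (−7.83 ± 0.61), Fabp7 (−9.49 ± 0.59), Hes5 (−7.96 ± 0.47), Hoxb2 (−5.12 ± 0.44), Krt8 (−5.50 ± 0.36) and Wnt3a (−8.09 ± 0.41). Gate and medium differed between these changes too.

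Rows without a gene name, which no comparison used, held 1.81% of the CPM in Sox2 48 h replicate 2, against at most 1.31% in NMP libraries.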

How the results depend on the processing

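The voom fit and the list tests without a library were chosen after the data were seen, and the other alternatives before. Gene counts stayed within 1.5 times the reported ones in 118 of 151 cases and moved by more in 33. With array weights, whose fit did not converge fully, the counts were 3510 for Sox2 48 h against NMP, 4834 for Tbxt 48 h against NMP, 1221 for Tbxt 48 h against Sox2 48 h, 4032 for DN against Sox2+, 3908 for FGF/CHIR against FGF and 5592 for Tbxt 7 d against FGF/CHIR DN. The fit of the compared groups alone gave 1760 for Sox2 48 h against NMP, 1051 for Tbxt 48 h against Sox2 48 h, 1179 for DN against Sox2+ and 558 for Tbxt 7 d against FGF/CHIR DN. The 2-fold minimum, which can only lower counts, gave 1363 for Tbxt 48 h against NMP, 1944 for FGF Sox2+ against Sox2 48 h, 4093 for Tbxt 7 d against Tbxt 48 h, 3403 for Tbxt 7 d against FGF Sox2+, 1079 for DN against Sox2+ and 1156 for FGF/CHIR against FGF. A filter at 20 CPM, with fewer genes tested, gave 668 for Sox2 48 h against NMP, and no filter 2771 for FGF/CHIR against FGF. Other causes were not tested.

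Leaving out 1 library gave 316 to 749 genes for Sox2 48 h against NMP, 709 to 2079 for Tbxt 48 h against NMP, 132 to 492 for Tbxt 48 h against Sox2 48 h and 1456 to 2920 for FGF Sox2+ against Sox2 48 h. The ranges were 5136 to 7268 for Tbxt 7 d against Tbxt 48 h, 4953 to 6521 for Tbxt 7 d against FGF Sox2+, 1414 to 2266 for DN against Sox2+, 1765 to 1831 for FGF/CHIR against FGF, 1378 to 3193 for Tbxt 7 d against FGF/CHIR DN and 2595 to 5185 for the difference of changes. A group left with 1 library was assumed to vary like the others. The replicate block on the library number, over 12 libraries, gave 683, 1717, 354, 2747, 6353, 5394 and 3522 genes for the comparisons without groups of 1 library, in the order of the report. Residuals of libraries with the same number in different groups correlated at a median of −0.08 (21 pairs) against 0.02 for other pairs (36 pairs), across genes, which are not independent replicates. NMP and Tbxt 48 h libraries of the same number correlated at 0.48 and 0.46. In 8 of 12 libraries the best match shared the number, all between NMP and Tbxt 48 h or Sox2 48 h and FGF Sox2+. Residuals in groups of 2 mirror each other, so these are not independent. Shared inductions stay open.

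List tests gave 134 and 16 calls with preset and estimated correlation. Without Tbxt 7 d replicate 1 they gave 144 and 17, and without FGF Sox2+ replicate 2 133 and 30. The named genes, reporters aside, were chosen among those that stayed on their side of the threshold throughout, so their stability is no finding. Sox2 in Sox2 48 h cells against NMPs changed sign with array weights (−0.03) and without NMP replicate 1 (−0.08, against at most 0.19 without another library). The planned edgeR count test was not run, since whole reads were not recovered. Depth limits FGF Sox2+ replicate 2 most, where 3 reads equal 3.76 CPM.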

Other observations

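All tests and gene choices of this part were made after the results were seen. The matrix gene Sparc was 8327 CPM in FGF DN cells and 1945 CPM in FGF/CHIR DN cells, against 331 and 373 CPM in the FGF Sox2+ libraries and 148 CPM in the FGF/CHIR Sox2+ library. In the same order, the laminin gene Lamc1 was 2277, 155, 51.0, 88.9 and 57.9 CPM, and the collagen gene Col4a1 was 2864, 516, 41.4, 57.6 and 15.3 CPM. The nidogen gene Nid1 was 466, 80.7, 15.5, 26.3 and 5.55 CPM, and Nid2 was 200.2, 120.2, 85.3, 97.7 and 98.99 CPM.

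WNT and FGF target genes of Tbxt 7 d replicate 1 stood apart from replicates 2 and 3. Depth or scaling would move both lists alike, but the median log2 difference of the FGF list exceeded that of the WNT list by 2.49, with medians of 1.9 and −0.6. The immediate early and stress list was higher in replicate 1 too, with a median of 1.12, above all 10000 random lists (5 higher and 0 lower of 9 genes by over 2-fold), and handling of the cells was not tested. A swap with a library of another group is argued against by its correlations across genes, at most 0.894 with other groups and at least 0.943 with its own. Weaker CHIR action in its culture stays open: the 9 WNT targets that were higher with CHIR in Sox2-derived cultures had a median difference of −2.29, but the 10 Hox genes that were higher there had one of 2.24. No label separates the libraries, and no other biological explanation was tested.

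Endoderm genes were high in both DN libraries of the 7 d Sox2-derived cultures. Pluripotent cells carried into the DN gate cannot be told apart from other sources without a library of such cells: 12 of 20 naive pluripotency and epiblast genes were over 2-fold higher in DN cells in each medium, but Sox2 differed by −3.7 in FGF and −5.05 in FGF/CHIR, and the gate excludes mCherry. The kind of endoderm stays open among primitive and parietal, visceral and gut. Without the filter, medians of the added primitive and parietal list (18 genes) were 4.86 in FGF (17 higher and 0 lower by over 2-fold) and 2.64 in FGF/CHIR (15 and 0). Those of the visceral list (16 genes) were 2.39 in FGF (11 higher and 0 lower by over 2-fold) and 2.55 in FGF/CHIR (11 and 0), and those of the gut list (15 genes) 0.7 in FGF (7 higher and 4 lower by over 2-fold) and 0.0 in FGF/CHIR (0 and 2). Random lists decide nothing here, as the filter favours genes high in DN cells. Of 10000, 5 reached the median of the filtered gut list in FGF and 1638 in FGF/CHIR. Not every visceral member was high. In FGF DN and FGF/CHIR DN cells, the members Afp and Apob were 4.54 and 0 CPM and 0 and 0 CPM. Past the filter, 5, 1 and 3 genes of these lists stood at 20 CPM or more in every Sox2+ library, and 2, 4 and 2 were in fixed lists.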
